A study of Mus musculus with 12 samples.

How the data were processed

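Bulk RNA sequencing had been done on 12 tumour samples of a mouse model of intrahepatic cholangiocarcinoma after 8 days of treatment. Total RNA had been extracted and made into stranded libraries with Qiagen kits, per the labels' protocols. Samples were assigned to Control, GC, ICB and Combination (3 each) from their titles, and 0 columns stayed unmapped. The replicate numbers used are those of the titles, which differ from the numbers in the description field. The labels give no batch, no sequencing date and no link of samples to animals.

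The values used were FPKM (fragments per length of transcript and per total of mapped fragments) as deposited by the authors, 1 value per gene symbol and sample. Per the submitters' processing notes, FastQC, cutadapt, HISAT2, SAMtools and HTSeq were used with the mm10 mouse genome. The notes give no versions, do not say which step made FPKM, and do not say whether strand was used in counting, so overlapping and antisense genes cannot be told apart. FPKM values keep the authors' scaling and no further scaling was applied in the main results. The smallest values (up to 0.1 FPKM) were compared between pairs of samples, over 66 pairs, to look for whole-read steps. The fullest bin of log2 ratios (width 0.1) held a median of 11.1% and at most 17.3% of genes, so whole reads could not be recovered, depth is unknown and count models were not used.

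Values were analysed as log2(FPKM + 1) in R 4.3.3 with limma 3.58.1. Group means of all 12 samples were fitted together (8 residual degrees of freedom), with empirical Bayes moderation and an intensity trend. Contrasts were GC, ICB and Combination against Control, Combination against GC and against ICB, both main effects, their interaction and a moderated F over the groups. P-values were adjusted by the Benjamini-Hochberg method, with a threshold of 0.05 and no fold threshold. The comparisons, tests, alternatives, gene lists and naming rule were written before the data were examined, for values on the scale of counts: a mean of at least 10 for a gene to be tested and a group mean of at least 50 for a gene to be named. Since the unit was FPKM, a mean of at least 1 FPKM (12765 genes) and a group mean of at least 5 FPKM were used instead, a change made before any test was run. A mean of at least 10 FPKM (6433 genes) was kept as an alternative.

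Gene lists (65 lists of cell type markers and pathways, 1050 entries) had been fixed beforehand. Of the entries 1017 were found, 16 of them through an older symbol, and 61 lists had at least 3 tested members. The lists for pancreatic acinar cells, B cells, NK cells and mitochondrially encoded transcripts had fewer and were not tested. Lists were tested with camera, which compares the members of a list with the other tested genes, at a preset correlation of 0.01. They were tested again with an estimated correlation, and with fry. Members were also adjusted over the list alone. A list of 17 small intestinal genes was written after intestinal transcripts had been seen in Combination replicate 1. Which of the called lists the text describes was chosen after their values were seen.

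Genes were named by rule. In each comparison the rule took, among called genes whose samples on both sides did not overlap (within each stratum for main effects) and whose higher group mean reached that floor, up to 8 with the largest rise and up to 8 with the largest fall, leaving out names that are only model or clone names. Chance separates 3 samples from 3 in this way 10% of the time. If fewer than 5 passed, the genes of smallest p up to 5 each way were taken. The rule also took up to 4 members of smallest p in each called list, and in each comparison with Control a fixed set of checkpoint, lymphocyte, proliferation, p53, biliary and hepatocyte genes. Genes of liver, intestine, muscle and ribosomal precursor RNA given per library, and the pair Rps27 and Rps27rt, were chosen after their values were seen. Some genes that the rule took are not reported here. Of the symbols, 23334 were found once in GENCODE M21 (GRCm38), and 340 of 344 named genes received a location from it.

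Separation of the groups was tested with a pseudo-F on Euclidean distances and a one-sided permutation test with 100000 resamples. Differences without and with the other treatment were correlated across genes. On simulated data for GC against Control (12765 genes, 200 changed), the limma step recovered 20% of genes changed 2-fold, 84% changed 4-fold, 92% changed 8-fold and 96% changed 16-fold, with 12 unchanged genes called. With no change simulated limma called 1 gene for GC against Control, 1 for Combination against ICB and 0 in the other comparisons, and camera called 2 lists for GC against Control. The simulated noise was normal and independent between genes, without tissue differences between libraries, and only genes above a floor of expression were changed. These figures therefore do not give the power or the false gene and list calls of the real libraries.

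Alternatives were other pseudocounts, filters, TMM and quantile scaling, no intensity trend, sample weights, replicate blocks, the mean of the hepatocyte list as a covariate, fits of only the compared groups, a mean of at least 10 or 50 FPKM, leaving out each library in turn and, for the separation, Spearman distances and only the genes of largest variance. The hepatocyte share of FPKM as a covariate, a pseudocount of 0.1 and leaving out the muscle-rich, liver-rich or all Combination libraries were added after the data were seen. Figures were drawn with matplotlib 3.10.9 and pandas 2.3.3.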

Results

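Transcript levels were measured by bulk RNA sequencing of total RNA from 12 tumours of a mouse model of intrahepatic cholangiocarcinoma, the cancer of the bile ducts inside the liver. The tumours were collected after 8 days of treatment in 4 groups of 3 samples. Control tumours received control immunoglobulin, GC tumours received chemotherapy (the labels give only the abbreviation, read here as gemcitabine plus cisplatin), ICB tumours received dual immune checkpoint blockade (the series title names CTLA-4 blockade and anti-PD1 therapy) and Combination tumours received both. The deposited values were FPKM for 24421 gene symbols, of which 5749 were listed at 0 in all 12 libraries. FPKM summed to between 547146 and 660067 per library, and between 14533 and 16442 symbols were above 0. Read counts were not recoverable from these values, so the sequencing depth is unknown and no counting intervals are given. The labels do not say that the samples came from separate animals, so p-values measure the spread between these samples. Levels are mean ± SD FPKM of n = 3 libraries unless stated, and differences are limma estimates ± SE on log2(FPKM + 1), a scale that understates changes of weakly expressed genes.

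Transcripts of hepatocytes, small intestine and skeletal muscle differed strongly between libraries. The hepatocyte list (20 genes, among them albumin and apolipoproteins) made up 0.00195% to 0.0151% of FPKM in Control, 0.137% to 1.13% in GC, 0.0636% to 0.393% in ICB, and 0.752%, 18.4% and 7.39% in Combination replicates 1, 2 and 3. Alb, the main plasma protein made by hepatocytes, stood at 217, 45398.5 and 16866.5 FPKM in those Combination libraries against 20.7 ± 16.4 FPKM in Control. Combination replicate 1 held small intestinal transcripts instead, with the intestinal fatty acid-binding gene Fabp2 at 1779 FPKM and the retinol-binding gene Rbp2 at 1051 FPKM. Its mean log2 value over 17 small intestinal genes was 6.82 against at most 0.64 in the other libraries. Skeletal muscle transcripts were high in Control replicate 2 (list mean 6.55) and GC replicate 2 (8.08), where the muscle actin gene Acta1 reached 348 and 937 FPKM, and at most 0.58 elsewhere. ICB replicates 2 and 3 carried the most ribosomal precursor RNA, with Rn45s at 26773 and 8744 FPKM against at most 3901 in other libraries.

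**Figure D1:**
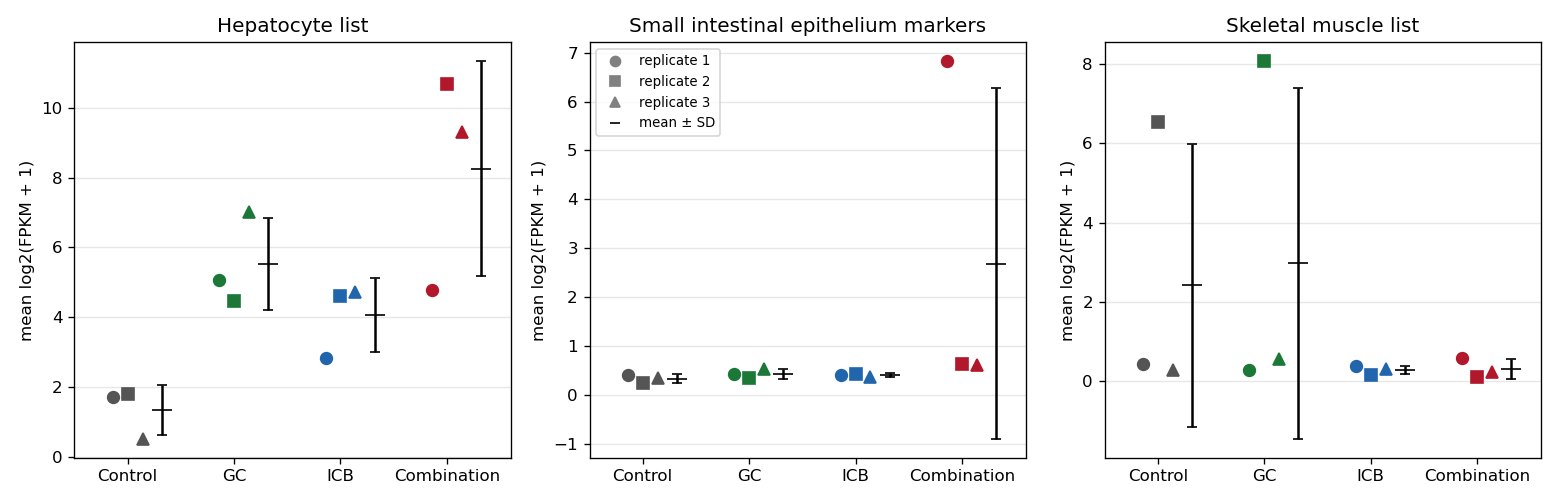
Mean log2(FPKM + 1) of the hepatocyte, small intestinal and skeletal muscle gene lists (y axis) in each of the 12 libraries (points), by treatment group. Hepatocyte values ran from 0.52 in Control replicate 3 to 10.67 in Combination replicate 2, the intestinal value of Combination replicate 1 was 6.82, and the muscle values of Control replicate 2 and GC replicate 2 were 6.55 and 8.08.

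The 4 groups lay apart as a whole (pseudo-F 2.56, one-sided permutation test with 100000 resamples, p = 0.00752), and without Combination replicate 1 the pseudo-F was 5.02. The first principal component took 54.9% of the variance and the second 13.4%. Scores on the first were 170 and 81.9 in Combination replicates 2 and 3, 14.9 in GC replicate 3 and from -52.1 to -12.6 elsewhere. Hepatocyte list means were highest in those same Combination and GC libraries (10.7, 9.30 and 7.01), so the separation does not tell treatment from tissue content. Spearman correlations between libraries of a group had a median of 0.929 and ranged from 0.614, between Combination replicates 1 and 2, to 0.972. Of 12765 genes with a mean of at least 1 FPKM, 233 differed among the 4 groups (limma moderated F, adjusted p under 0.05). That count was 1806 without Combination replicate 1 and 131 to 176 without any other single library.

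What chemotherapy alone did was read from GC against Control. Type I interferon response genes, the antiviral program induced by interferons alpha and beta, were higher in GC tumours as a group, with a median log2 difference of 2.10 over 23 genes (adjusted p = 0.346 with an estimated correlation). Isg15, a ubiquitin-like antiviral protein, stood at 4.08 ± 1.30 FPKM in Control and 43.7 ± 23.3 FPKM in GC, with all 3 GC libraries above all 3 Control libraries. Ifit3 stood at 0.562 ± 0.761 and 13.7 ± 10.4 FPKM, and Irf7, the transcription factor that amplifies interferon production, at 2.10 ± 1.91 and 33.1 ± 32.6 FPKM. The single gene past the threshold was Cygb, cytoglobin, a haem protein of stellate cells and fibroblasts (chromosome 11, 116645595 to 116654313, GRCm38, GENCODE M21), which rose from 4.96 ± 1.55 to 39.1 ± 6.38 FPKM.

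Among the gene lists fixed beforehand, 22 were higher and 4 lower in GC than in Control by camera with a preset correlation of 0.01. In the type I interferon list (adjusted p = 1.22e-22, adjusted p = 0.346 with an estimated correlation) 22 of 23 members were positive, 0 passed over all genes, and 21 rose and 0 fell when adjusted over the list alone. Isg15 differed by 3.05 ± 0.49, Ifit3 by 3.11 ± 0.52 and Ifit1 by 2.48 ± 0.41 (limma adjusted p = 0.0869 each). The interferon gamma response list had a median of 1.22 over 23 genes (adjusted p = 1.53e-10, adjusted p = 0.385 with an estimated correlation), with 11 members up and 0 down when adjusted over the list alone. MHC class I genes, which present peptides to CD8 T cells, had a median of 0.84 over 22 genes (adjusted p = 8.22e-08, adjusted p = 0.385 with an estimated correlation), 4 up and 0 down when adjusted over the list alone. Their member Tap2, the peptide transporter subunit, differed by 1.21 ± 0.26. Fibroblast genes had a median of 1.27 over 18 genes (adjusted p = 3.36e-06, adjusted p = 0.482 with an estimated correlation). In it 5 were up and 0 down when adjusted over the list alone, led by the proteoglycan Lum (12.8 ± 10.03 and 84.9 ± 23.3 FPKM) and Cthrc1 (13.3 ± 16.3 and 105 ± 33.2 FPKM). Mature migratory dendritic cell genes had a median of 0.99 over 9 genes (adjusted p = 0.00283, adjusted p = 0.385 with an estimated correlation), 4 up and 0 down when adjusted over the list alone. The chemokine Ccl22 stood at 0.493 ± 0.228 and 4.62 ± 2.04 FPKM and the chemokine receptor Ccr7 at 0.669 ± 0.191 and 3.02 ± 0.781 FPKM. Hepatocyte genes had a median of 4.72 (adjusted p = 4.44e-14, adjusted p = 0.385 with an estimated correlation), 16 up and 0 down when adjusted over the list alone. Every GC library held more of them than every Control library. The muscle-rich libraries were 1 Control and 1 GC sample. Among the other genes of smallest p, which did not pass, were Fabp1, a fatty acid carrier of liver and intestine (5.72 ± 0.77, limma adjusted p = 0.0724) and Wnt4 (3.10 ± 0.47, adjusted p = 0.0869). The ribosomal gene Rps27 was listed at 16 to 19 FPKM in all GC libraries and ICB replicate 1 and at 1154 to 10023 FPKM in the other 8. Its near-identical copy Rps27rt took the opposite pattern, so both are uncertain.

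Limma called 1 gene up and 0 down between GC and Control, with 1259 genes at an unadjusted p under 0.05. Cygb (2.77 ± 0.33, limma adjusted p = 0.0361) missed the threshold without Control replicate 2 or 3, GC replicate 1, 2 or 3, ICB replicate 2 or Combination replicate 3 (adjusted p up to 0.277, without GC replicate 3). It also missed it under TMM or quantile scaling, without an intensity trend, without the muscle-rich pair and with only these groups in the fit (limma adjusted p from 0.0506 to 0.4305), where other genes made up a count of 3. The count was 183 without Combination replicate 1, 5 without Control replicate 1 or ICB replicate 1, 297 without the 3 Combination libraries, 574 with the hepatocyte list mean as a covariate, 0 under TMM or quantile scaling and 0 without the muscle-rich pair.

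What dual blockade alone did was read from ICB against Control, where no gene passed. Limma called 0 genes up and 0 down, with 223 genes at an unadjusted p under 0.05 and a smallest adjusted p of 1. Neutrophil genes were higher as a group, with a median of 1.17 over 14 genes, 12 of them positive and 0 past the threshold (adjusted p = 0.26 with an estimated correlation). The mean log2 value of the list relative to Control was 2.30 in ICB replicate 3 and 0.51 and 0.65 in ICB replicates 1 and 2. The calcium-binding alarmin S100a9 stood at 24.3 ± 21.3 FPKM in Control and 164 ± 205 FPKM in ICB, and the granule protein Lcn2 at 54.8 ± 89.8 and 159 ± 78.5 FPKM. T cell receptor complex genes were close to the detection floor: Cd3d stood at 0.072 ± 0.125 FPKM in Control and 2.03 ± 2.23 FPKM in ICB. Cd274, which encodes the checkpoint ligand PD-L1, stood at 6.94 ± 0.839 and 10.8 ± 1.93 FPKM (0.57 ± 0.33).

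By camera 34 lists were higher and 2 lower in ICB than in Control. Neutrophil genes (adjusted p = 1.9e-07, adjusted p = 0.26 with an estimated correlation) had 0 members past the threshold over all genes or when adjusted over the list alone. The T cell list had a median of 1.00 over 5 genes (adjusted p = 7.27e-07, adjusted p = 0.26 with an estimated correlation), with 1 member up when adjusted over the list alone. Lat, an adaptor of the T cell receptor, stood at 0.458 ± 0.323 and 2.83 ± 1.47 FPKM. The T cell list's mean log2 value, relative to the Control mean, ran from -0.11 to 0.13 over Control libraries and unevenly from 0.44 to 1.86 over ICB libraries. MHC class II genes, which present peptides to CD4 T cells, had a median of 0.64 over 10 genes (adjusted p = 7.27e-07, adjusted p = 0.279 with an estimated correlation) and 0 members past either threshold. Their chaperone Cd74 stood at 67.4 ± 62.1 and 181 ± 93.1 FPKM and H2-Ab1 at 35.7 ± 32.5 and 92.4 ± 48.1 FPKM. The mean log2 value of the class II list, relative to the Control mean, ran from -1.23 to 0.94 over Control libraries and from 0.64 to 1.38 over ICB libraries. The type I interferon list, with 0 members past either threshold, had a median of 0.22 (adjusted p = 0.00322, adjusted p = 0.558 with an estimated correlation), and without Control replicate 3 its adjusted p was 0.1. Hepatocyte genes had a median of 2.83 (adjusted p = 1.69e-19, adjusted p = 0.26 with an estimated correlation), 6 up and 0 down when adjusted over the list alone. Every ICB library held more of them than every Control library. The base excision repair gene Apex1 (54.9 ± 11.2 and 18.5 ± 4.69 FPKM) was among the lower genes of smallest p, with limma adjusted p = 1. The checkpoint receptors Pdcd1 and Ctla4 and the lymphocyte genes Cd8a, Cd4, Foxp3 and Ifng had means under 1 FPKM over the 12 libraries and were not tested. Leaving out any single library left the count at 0, and sample weights, highest for ICB replicate 3, raised it to 1277.

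What both treatments together did was read from Combination against Control. Fabp1 rose from 2.52 ± 2.78 to 4120 ± 2141 FPKM (chromosome 6, 71199827 to 71205023). Ogn, a matrix proteoglycan (chromosome 13, 49608046 to 49624501), fell from 10.9 ± 3.5997 to 1.19 ± 0.68 FPKM. Gclm, a subunit of the enzyme that limits glutathione synthesis (chromosome 3, 122245557 to 122270732), rose from 9.44 ± 0.541 to 39.4 ± 16.3 FPKM. The checkpoint ligands Ceacam1 (chromosome 7, 25461707 to 25477603; 1.18 ± 0.591 to 19.7 ± 12.9 FPKM) and Lgals9, galectin-9 (chromosome 11, 78962974 to 78984946; 22.6 ± 6.20 to 161 ± 128 FPKM), rose as well.

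Camera called 17 lists higher and 3 lower in Combination than in Control. Of the 20 hepatocyte genes 17 rose over all genes and 19 when adjusted over the list alone, with a median of 7.27 (adjusted p = 2.4e-21, adjusted p = 0.421 with an estimated correlation). The type I interferon list had a median of 1.34 (adjusted p = 1.33e-11, adjusted p = 0.421 with an estimated correlation), with 6 of 23 members up and 0 down over all genes, and 16 up and 1 down when adjusted over the list alone. Irf7 rose to 22.03 ± 9.91 FPKM (2.95 ± 0.63, limma adjusted p = 0.0242) and the interferon-induced chaperone Rtp4 from 0.597 ± 0.153 to 6.31 ± 1.89 FPKM (2.17 ± 0.43, limma adjusted p = 0.018). MHC class I genes had a median of 0.86 (adjusted p = 1.75e-07, adjusted p = 0.421 with an estimated correlation), with 2 of 22 up over all genes and 5 up when adjusted over the list alone. The class I heavy chain H2-K1 rose from 105 ± 2.32 to 492 ± 222 FPKM. CD8 T cell and cytotoxic effector genes had a median of 1.99 over 4 genes (adjusted p = 0.000595, adjusted p = 0.421 with an estimated correlation), with 0 past the threshold over all genes and 4 up when adjusted over the list alone. Their granule protease Gzmb stood at 0.0199 ± 0.0345 and 2.96 ± 1.88 FPKM (limma adjusted p = 0.0631), and Gzma was listed at 0 in all Control libraries and was highest in the intestine-rich Combination replicate 1. Platinum transport and detoxification genes had a median of 0.53 over 11 genes (adjusted p = 0.00192, adjusted p = 0.421 with an estimated correlation). In it 3 rose: Gclm, the copper and cisplatin importer Slc31a1 (10.4 ± 2.92 to 28.1 ± 7.93 FPKM), and the export pump Abcc2, which was listed at 0 in the Control libraries and at 3.93, 34.99 and 25.03 FPKM in Combination. The NRF2 target list, an antioxidant program, had a median of 0.27 over 16 genes (adjusted p = 0.00916, adjusted p = 0.421 with an estimated correlation), 2 up over all genes and 5 up when adjusted over the list alone. Checkpoint ligands had a median of 0.40 over 10 genes (adjusted p = 0.0127, adjusted p = 0.421 with an estimated correlation), and 3 rose (Ceacam1, Lgals9 and the LAG-3 ligand Fgl1). Cd274 was at 4.50 ± 2.43 FPKM (-0.65 ± 0.33, limma adjusted p = 0.234). Ribosomal protein genes were lower as a group, with a median of -1.41 over 21 genes (adjusted p = 1.75e-07, adjusted p = 0.66 with an estimated correlation), 0 past the threshold over all genes and 21 down when adjusted over the list alone. Liver and intestinal transcripts were highest in these same Combination libraries. The proliferation gene Mki67 (-0.41 ± 0.73), the p53 target Cdkn1a (-0.10 ± 0.39) and the biliary keratin Krt19 (1.97 ± 1.16) were not called. The signs of Mki67, Cdkn1a and Cd274 changed between processing settings.

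Limma called 453 genes up and 51 down between Combination and Control, with 3359 at an unadjusted p under 0.05. Fabp1 (10.35 ± 0.77, limma adjusted p = 0.000156), Ogn (-2.45 ± 0.31, adjusted p = 0.00116), Ceacam1 (3.12 ± 0.43, adjusted p = 0.00202), Gclm (1.87 ± 0.29) and Abcc2 (adjusted p = 0.00376 each) passed without any single library. Since every Combination library was rich in liver or intestinal transcripts, such fits do not test tissue content. Lgals9 (2.53 ± 0.47, limma adjusted p = 0.0131) missed the threshold without Control replicate 1 (0.0656), and Irf7 without Control replicate 1 or 3 or Combination replicate 2 (up to 0.105). H2-K1 (2.12 ± 0.44, limma adjusted p = 0.0218) and Rtp4 missed it without any Control library or Combination replicate 2 (up to 0.0818 and 0.0727). Slc31a1 (1.35 ± 0.28, limma adjusted p = 0.021) missed it without Control replicate 1 or 2 or Combination replicate 2 (up to 0.0806). Fgl1 (limma adjusted p = 0.0218) missed it without any Control library or Combination replicate 2 or 3 (up to 0.0843). The checkpoint ligand list missed it without Combination replicate 1 (0.081). The count was 229, 219 and 221 without Control replicates 1, 2 and 3, and 3167, 267 and 332 without Combination replicates 1, 2 and 3. Without both liver-rich libraries only the intestine-rich replicate 1 was left in Combination, so no count is given for that fit. The count was 149 without the muscle-rich pair, 239 with the hepatocyte list mean as a covariate (41 of them among the 504, 40 in the same direction) and 94 with only these groups in the fit. Under that covariate Fgl1 turned to -0.75 and the platinum list's test pointed down with a median of 0.34. Falls outnumbered rises without Combination replicate 1 (1406 up, 1761 down) and with sample weights (1666 up, 2603 down). Those weights strongly favoured Combination replicate 3. Quantile scaling gave 447 up and 411 down.

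**Figure D2:**
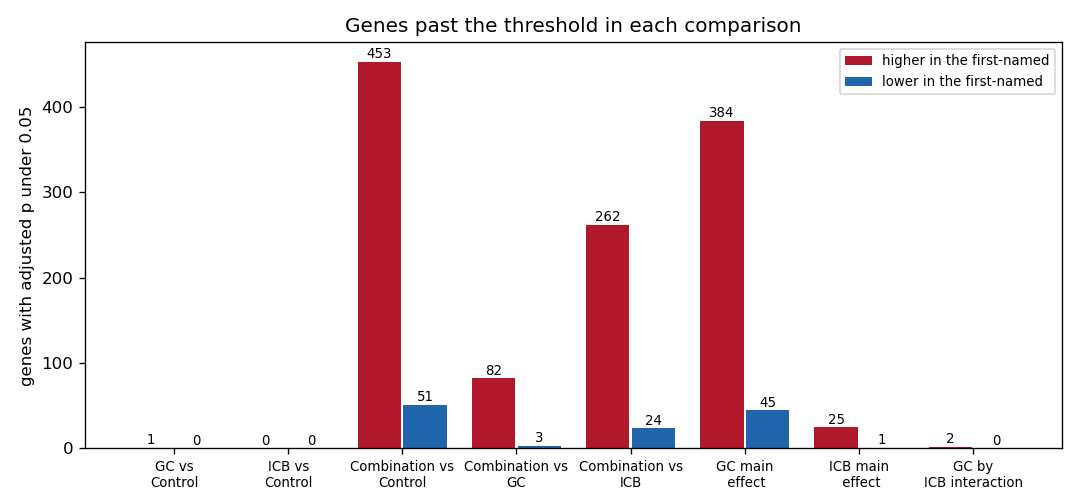
Genes called up and down by limma (adjusted p under 0.05, 12765 genes tested; bars, number of genes on the y axis) in each comparison. Combination against Control had 453 up and 51 down, and the chemotherapy main effect 384 up and 45 down, while ICB against Control had 0.

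What blockade added to chemotherapy was read from Combination against GC. Pigr, the receptor that carries immunoglobulin A across epithelia (chromosome 1, 130826684 to 130852249), rose from 5.01 ± 3.55 to 252 ± 179 FPKM, and Fabp1 rose from 199 ± 187 FPKM. Cygb fell from 39.1 ± 6.38 to 10.2 ± 2.88 FPKM. Fibroblast genes were lower as a group (median -1.78 over 18 genes, adjusted p = 0.000376, adjusted p = 0.9 with an estimated correlation), with 0 past the threshold over all genes and 7 down when adjusted over the list alone. The collagens Col1a1 (1220 ± 420 and 340 ± 250 FPKM) and Col3a1 (838 ± 254 and 220 ± 135 FPKM) led that list with limma adjusted p = 0.208 and 0.143, and without the liver-rich Combination replicate 2 the median for fibroblasts was -1.04. Hepatocyte genes had a median of 2.83 (adjusted p = 3.48e-13, adjusted p = 0.668 with an estimated correlation), 0 past the threshold over all genes and 6 up when adjusted over the list alone. Their median turned to -1.48 without the liver-rich Combination replicates 2 and 3, which left only the intestine-rich replicate 1 in that group.

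By camera 8 lists were higher and 3 lower, and limma called 82 genes up and 3 down, with 2105 at an unadjusted p under 0.05. Pigr (5.26 ± 0.62, limma adjusted p = 0.00284) passed without any single library. Each Combination library was rich in liver or intestinal transcripts, so leaving out a single library does not remove them. Fabp1 (4.63 ± 0.77, limma adjusted p = 0.0234) missed the threshold without GC replicate 1 or 2 or Combination replicate 2 or 3 (up to 0.131). Cygb (-1.86 ± 0.33, limma adjusted p = 0.0291) missed it without Control replicate 2, any GC library, ICB replicate 1 or Combination replicate 2 (up to 0.126). Another lower gene was the uncertain copy Rps27rt. The count was 3014 without Combination replicate 1, 78 without GC replicate 3, 24 and 31 without GC replicates 1 and 2, and 40 to 56 without any other library. It was 260 without the liver-rich pair (43 of them among the 85) and 15 without the muscle-rich pair. Falls outnumbered rises without Combination replicate 1 (1118 up, 1896 down) and with sample weights (1405 up, 2623 down).

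What chemotherapy added to blockade was read from Combination against ICB. Pigr rose from 1.63 ± 1.42 FPKM, Fabp1 from 44.1 ± 26.2 FPKM and Gclm from 8.07 ± 1.53 FPKM. The neutrophil-attracting chemokine Cxcl2 (chromosome 5, 90903871 to 90905938) fell from 22.6 ± 7.10 to 1.85 ± 1.98 FPKM and the decoy interleukin 1 receptor Il1r2 fell from 11.97 ± 5.12 to 1.46 ± 1.06 FPKM. Both belong to the neutrophil list, which had a median of -1.33 over 14 genes (adjusted p = 0.00366, adjusted p = 0.75 with an estimated correlation), 2 down over all genes and 2 down when adjusted over the list alone. The type I interferon list had a median of 1.24 (adjusted p = 9.49e-10, adjusted p = 0.75 with an estimated correlation), with 1 member, Irf7 (2.20 ± 0.982 to 22.03 ± 9.91 FPKM), up over all genes and 13 up when adjusted over the list alone. NRF2 targets had a median of 0.79 over 16 genes (adjusted p = 0.000259, adjusted p = 0.463 with an estimated correlation), 2 up over all genes, and 8 up and 1 down when adjusted over the list alone. Hepatocyte genes had a median of 4.77 (adjusted p = 7.89e-13, adjusted p = 0.75 with an estimated correlation), with 6 up over all genes and 15 when adjusted over the list alone.

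By camera 10 lists were higher and 7 lower, and limma called 262 genes up and 24 down, with 2616 at an unadjusted p under 0.05. Pigr (6.48 ± 0.62, limma adjusted p = 0.000489), Fabp1 (6.63 ± 0.77, adjusted p = 0.00137) and Gclm (2.09 ± 0.29, adjusted p = 0.00319) passed without any single library. Here too, leaving out a single library leaves liver or intestinal transcripts in Combination. Cxcl2 (-3.22 ± 0.66, limma adjusted p = 0.03) missed the threshold without Control replicate 3, any ICB library or Combination replicate 2 (up to 0.126). Il1r2 (-2.42 ± 0.56, limma adjusted p = 0.0487) missed it without any library except Control replicates 1 and 2 and Combination replicate 1 (up to 0.195). Irf7 (2.79 ± 0.63, limma adjusted p = 0.0445) missed it without Control replicate 1 or 3, GC replicate 3, any ICB library or Combination replicate 2 (up to 0.183). The neutrophil list missed it without ICB replicate 3 or Combination replicate 1 (up to 0.116). The count was 113, 108 and 130 without ICB replicates 1, 2 and 3, 2050 without Combination replicate 1 and 151 without Combination replicate 2. It was 152 without the muscle-rich pair and 27 with only these groups in the fit. The split was 1292 up and 758 down without Combination replicate 1, 1753 up and 1719 down with sample weights and 271 up and 225 down under quantile scaling.

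The effect of chemotherapy over both blockade states was read as the mean of GC minus Control and Combination minus ICB. Type I interferon genes were higher as a group: 15 of 23 rose over all genes and 0 fell, and 21 rose and 1 fell when adjusted over the list alone, with a median of 1.67 (adjusted p = 3.38e-17, adjusted p = 0.535 with an estimated correlation). Irf7 (chromosome 7, 141262706 to 141266481) rose by 2.99 ± 0.44, Isg15 (chromosome 4, 156199424 to 156200818) by 2.31 ± 0.35, Ifit3 (chromosome 19, 34583531 to 34588731) by 2.41 ± 0.37 and Rtp4 (chromosome 16, 23520291 to 23614222) by 1.98 ± 0.31. The mean log2 value of the list, relative to Control, was 1.90 ± 0.79 in GC, 0.23 ± 0.19 in ICB and 1.41 ± 0.47 in Combination (SD, n = 3). Ogn fell by 1.65 ± 0.22.

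**Figure D3:**
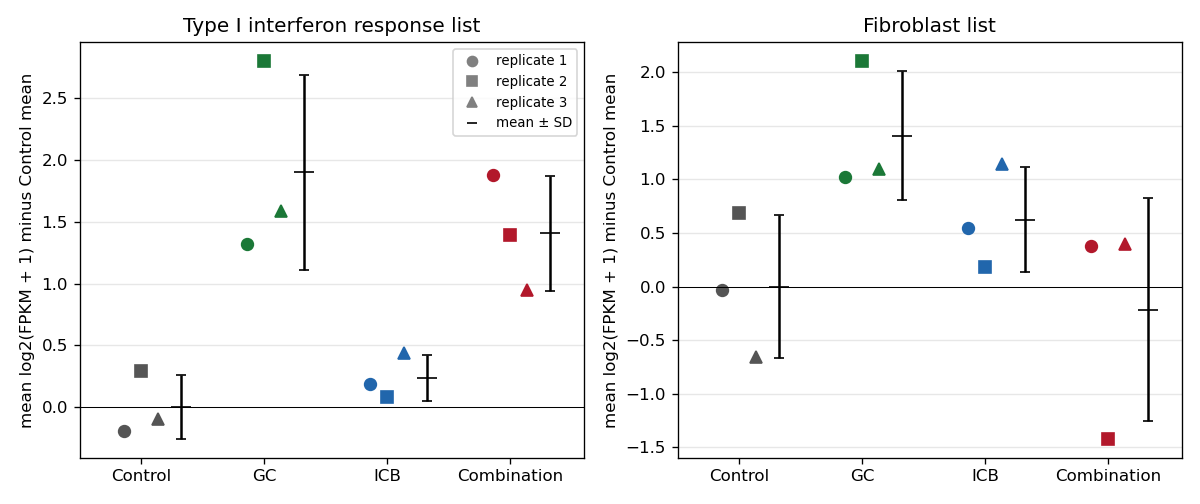
Mean log2(FPKM + 1) of the type I interferon and fibroblast gene lists minus the Control mean (y axis) in each library (points), with group mean ± SD (n = 3). The interferon means were 1.90 in GC, 0.23 in ICB and 1.41 in Combination, and the fibroblast means 1.41, 0.62 and -0.22, the last with replicate 2 at -1.42 and the others at 0.38 and 0.39.

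Interferon gamma response genes had a median of 0.98 (adjusted p = 2.78e-08, adjusted p = 0.535 with an estimated correlation), with 4 of 23 up over all genes and 16 up when adjusted over the list alone. MHC class I genes had a median of 0.67 (adjusted p = 2.78e-08, adjusted p = 0.535 with an estimated correlation), 2 of 22 up over all genes and 12 up when adjusted over the list alone, among them Tap2 (0.97 ± 0.19, limma adjusted p = 0.0192). CD8 T cell and cytotoxic effector genes had a median of 1.30 over 4 genes (adjusted p = 0.00836, adjusted p = 0.671 with an estimated correlation), 1 up over all genes and 4 up when adjusted over the list alone. NRF2 targets had a median of 0.41 (adjusted p = 0.0119, adjusted p = 0.535 with an estimated correlation), 2 up over all genes and 5 up when adjusted over the list alone, led by Gclm (1.28 ± 0.20, limma adjusted p = 0.00666). Checkpoint ligands had a median of 0.64 (adjusted p = 0.0124, adjusted p = 0.535 with an estimated correlation), 2 up over all genes and 4 up when adjusted over the list alone. Ceacam1 rose by 1.83 ± 0.30 and Lgals9 by 1.85 ± 0.33. Hypoxia response genes were lower, with a median of -0.96 over 17 genes (adjusted p = 4.13e-06, adjusted p = 0.671 with an estimated correlation), 1 down over all genes and 9 down when adjusted over the list alone. Bnip3, a mitophagy receptor, stood at 160 ± 91.8, 83.1 ± 37.2, 211 ± 35.1 and 77.9 ± 46.8 FPKM in Control, GC, ICB and Combination. Hepatocyte genes rose with a median of 4.40 (adjusted p = 3.04e-16, adjusted p = 0.535 with an estimated correlation), 11 of 20 over all genes and 19 when adjusted over the list alone.

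By camera 15 lists were higher and 3 lower, and limma called 384 genes up and 45 down, with 2846 at an unadjusted p under 0.05. Irf7 (limma adjusted p = 0.00492), Isg15 (0.00522), Ifit3 and Rtp4 (0.00602 each), Ogn (0.00361), Gclm and Ceacam1 (0.00895) passed without any single library. Leaving out a single library does not remove liver or intestinal transcripts from the Combination side of this effect. Lgals9 (0.014) missed the threshold without ICB replicate 2 (0.0504), and Tap2 without Control replicate 3, GC replicate 3 or ICB replicate 1 or 2 (up to 0.0681). The checkpoint ligand list missed it without Combination replicate 1 (0.0511). The count was 1737 without Combination replicate 1, 412 and 371 without Combination replicates 2 and 3, and between 162 (without GC replicate 3) and 245 (without GC replicate 1) without each of the other 9. It was 881 without the liver-rich pair (315 of them among the 429), 380 with the hepatocyte list mean as a covariate (53) and 113 without the muscle-rich pair. TMM scaling gave 276 up and 135 down, quantile scaling 381 up and 697 down, sample weights 1758 up and 1202 down, and the fit without Combination replicate 1 gave 1337 up and 400 down. Across genes, which are not independent replicates, the chemotherapy differences without and with blockade, which share no library, correlated at r = 0.508 (Spearman 0.418, 60.9% with the same sign), and at r = 0.2003 without the liver-rich pair.

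The effect of blockade over both chemotherapy states was read as the mean of ICB minus Control and Combination minus GC. Fabp1 rose by 4.18 ± 0.55, Creb3l3, a transcription factor of liver and intestine (chromosome 10, 81084324 to 81098874), by 2.48 ± 0.29, and Tm6sf2, a lipid export gene of the same tissues, by 1.87 ± 0.24. Hepatocyte genes had a median of 2.82 (adjusted p = 3.65e-25, adjusted p = 0.422 with an estimated correlation), 0 past the threshold over all genes and 16 up when adjusted over the list alone. CD8 T cell and cytotoxic effector genes had a median of 0.85 over 4 genes (adjusted p = 0.000456, adjusted p = 0.432 with an estimated correlation), with 0 past either threshold. Their mean log2 value relative to Control was 1.17 ± 0.92 in GC, 0.73 ± 0.57 in ICB and 2.13 ± 0.79 in Combination, where the intestine-rich replicate 1 was at 3.04 and replicates 2 and 3 at 1.602 and 1.75. Without that library the list's adjusted p was 0.0345.

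By camera 12 lists were higher and 3 lower, and limma called 25 genes up and 1 down, with 820 at an unadjusted p under 0.05. Fabp1 (limma adjusted p = 0.0198), Creb3l3 (0.0169) and Tm6sf2 (0.0198) each missed the threshold without GC replicate 1, ICB replicate 2, ICB replicate 3 or Control replicate 3. Fabp1 also did so without Control replicate 1 or GC replicate 2, Creb3l3 without Control replicate 2, and Tm6sf2 without Control replicate 1 or 2 or GC replicate 2. The highest limma adjusted p was 0.08, 0.0715 and 0.0733. The count was 0 without GC replicate 1, ICB replicate 2 or ICB replicate 3, 2 without any Control library or GC replicate 2, 41 without GC replicate 3, 11 without ICB replicate 1 and 1237 without Combination replicate 1. It was 228 without the liver-rich pair (24 of them among the 26) and 0 without the muscle-rich pair (limma, 331 at an unadjusted p under 0.05) or with the hepatocyte list mean as a covariate (565). The split was 838 up and 399 down without Combination replicate 1 and 1339 up and 2858 down with sample weights. The blockade differences without and with chemotherapy correlated across genes at r = 0.220 (Spearman 0.0190, 58.8% with the same sign), and at r = -0.183 without the liver-rich pair.

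Whether the combined effect departed from the sum of the single effects was tested as an interaction. Fibroblast genes departed downward as a group, with a median of -2.13 over 18 genes (adjusted p = 8.84e-08, adjusted p = 0.595 with an estimated correlation), 0 past the threshold over all genes and 6 down when adjusted over the list alone. Lum stood at 12.8 ± 10.03, 84.9 ± 23.3, 38.9 ± 19.0 and 20.9 ± 8.67 FPKM in Control, GC, ICB and Combination, and the mean log2 value of the list relative to Control was 1.41 ± 0.60 in GC, 0.62 ± 0.49 in ICB and -0.22 ± 1.04 in Combination, where the liver-rich replicate 2 was at -1.42 and replicates 1 and 3 at 0.38 and 0.39. Macrophage and monocyte genes had a median of -1.51 over 20 genes (adjusted p = 0.0034, adjusted p = 0.665 with an estimated correlation). Lysosomal Gpnmb stood at 3.35 ± 1.64, 9.33 ± 3.55, 5.72 ± 2.49 and 2.06 ± 1.39 FPKM. Regulatory T cell genes had a median of -1.37 over 8 genes (adjusted p = 0.00813, adjusted p = 0.595 with an estimated correlation), 3 down when adjusted over the list alone, with the co-stimulatory receptor Tnfrsf4 at 1.08 ± 0.599, 3.72 ± 1.15, 2.96 ± 1.38 and 1.56 ± 1.07 FPKM. Relative to the Control mean, the macrophage list ran from -1.30 to 0.66 over Control libraries. The regulatory T cell list ran from -1.43 to 0.44 over Combination libraries. The 2 genes past the threshold were Abcg5, a subunit of the sterol exporter of liver and intestine (chromosome 17, 84658234 to 84683011), and the drug-metabolising Cyp2b10 (chromosome 7, 25897620 to 25926624). Abcg5 was listed at 0 in the Control libraries, at up to 0.995 FPKM in GC and ICB libraries, and at 18.8, 15.98 and 16.6 FPKM in Combination.

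Limma called 2 genes up and 0 down for the interaction, with 1033 at an unadjusted p under 0.05, and camera called 6 lists up and 16 down. Abcg5 (limma adjusted p = 0.024) and Cyp2b10 (0.0278) missed the threshold without any Control library, GC replicate 1 or 2, or ICB replicate 2 or 3 (up to 0.133, without GC replicate 1). Abcg5 also did so without Combination replicate 3, and Cyp2b10 without GC replicate 3 or ICB replicate 1. The gene count was 0 without any Control library, GC replicate 1 or 2, or ICB replicate 2 or 3, 812 without Combination replicate 1 (571 up, 241 down) and 0 without the muscle-rich pair. The list count was 8 without Combination replicate 1, and the regulatory T cell list then missed the threshold (0.0969). Across all comparisons no list call held when camera estimated the correlation within each list. Fry, part of limma, tests whether the genes of a list move on balance in a single direction and does not compare them with other genes. It called 8 lists for the chemotherapy main effect, among them type I interferon (limma adjusted p = 0.0314). It called 1 for Combination against ICB (NRF2 targets, limma adjusted p = 0.0267) and 0 elsewhere. Its other test, for change in either direction, called 2 lists for GC against Control, 10 for Combination against Control, 3 for Combination against ICB, 10 for the chemotherapy main effect and 0 elsewhere. TMM scaling moved the median log2 difference of all genes from -0.29 to -0.04 for Combination against Control and from -0.36 to -0.01 for Combination against GC.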

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

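The tests below of intestinal tissue, of a wider processing difference and all regroupings of the samples were chosen after the result was seen, as was the use of the liver covariate and of scaling, both planned settings, to test the interferon genes; the tests of liver tissue for the Combination genes, of macrophage share and of reads shared between copies were written before it.

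The treatments' effects were compared with each other by the interaction test, which asks whether chemotherapy changed a gene or list differently with blockade than without it. Abcg5 departed upward by 3.61 and Cyp2b10 by 4.88 (outside Combination, Abcg5 was listed at up to 0.995 FPKM and Cyp2b10 at up to 0.0809 FPKM). Lists departed downward with a median log2 of -2.13 for fibroblasts, -1.52 for fibrillar collagens and matrix crosslinking, -2.01 for neutrophils, -1.51 for macrophages and monocytes, -1.89 for myeloid attracting chemokines and growth factors, -1.16 for alternatively activated macrophages, -1.38 for MHC class II and -1.78 for type 2 conventional dendritic cells. Further downward lists were NF-kB and TNF signalling (-0.85), regulatory T cells (-1.37), ribosomal proteins (-0.73), senescence (-1.07), type 1 conventional dendritic cells (-0.77), immunosuppressive mediators (-1.11), type I interferon (-0.87) and T cell exhaustion and checkpoint receptors (-0.94). Relative to the other genes, lists departed upward for NRF2 targets (0.64), mucin and intestinal epithelial genes (1.70), platinum transport and detoxification (0.36), oxidative phosphorylation (0.062), cholangiocyte and tumour epithelium (0.67) and the unfolded protein response (0.11). The median over all tested genes was -0.26, so a list near 0 can be called upward. None of these list calls held with an estimated correlation.

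The fibroblast, collagen, NRF2 target and macrophage and monocyte calls were kept without any single library. Without Combination replicate 1, the intestine-rich library, every other of these list calls except those of ribosomal proteins and platinum transport was lost. The adjusted p from camera in limma was then 0.0755 for myeloid attracting chemokines, 0.0763 for type 2 dendritic cells and MHC class II, 0.0872 for type 1 dendritic cells, 0.0969 for neutrophils and regulatory T cells, 0.112 for the mucin list, 0.124 for NF-kB signalling and 0.127 for alternatively activated macrophages. MHC class II was also lost without Control replicate 1, type 1 dendritic cells without Control replicate 1 or Combination replicate 3, and platinum transport without Control replicate 1 or Combination replicate 2 (up to 0.345). Ribosomal proteins were lost without Control replicate 2, GC replicate 1, ICB replicate 2 or Combination replicate 2 (up to 0.193), and senescence without Control replicate 3 or ICB replicate 2 (up to 0.109). Immunosuppressive mediators were lost without ICB replicate 2 or 3 or Combination replicate 2 (up to 0.153), and oxidative phosphorylation without Control replicate 3, ICB replicate 3 or Combination replicate 2 (up to 0.381). The checkpoint receptor list was lost without Control replicate 1, GC replicate 2, ICB replicate 3 or Combination replicate 2 (up to 0.168), and the cholangiocyte list without Control replicate 1, GC replicate 2, ICB replicate 1 or Combination replicate 2 (up to 0.396). The unfolded protein response was lost without Control replicate 1, GC replicate 1 or 2, ICB replicate 1 or Combination replicate 2 (up to 0.420), and type I interferon without Control replicate 1 or 3, GC replicate 2, ICB replicate 2 or 3 or Combination replicate 3 (up to 0.611).

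Of the 453 genes higher in Combination than in Control, 17 belong to the hepatocyte list and 436 do not. If adjacent liver in the samples raised them, they would follow the hepatocyte list within GC and within ICB as well, where Combination plays no part. Over 6 GC and ICB libraries the median within-group correlation of the 436 was 0.665 (quartiles 0.129 and 0.872), against -0.411 for the other tested genes and -0.237 for genes lower in Combination. In Combination replicates 2 and 3, with intestinal means of 0.64 and 0.61 against 6.82 in replicate 1, the 453 genes rose over Control by a median of 3.57 (quartiles 2.27 and 5.98) against 1.99 in replicate 1. A gene raised in replicate 1 alone would hardly have been called, so these rises were largely fixed by the calling and do not decide on intestine. A larger share of liver tissue could give the within-group correlations above. Whether treatment or dissection set that share, and whether intestine added to the 52 genes highest in replicate 1, stays open and untested.

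The type I interferon list was higher with chemotherapy (median 1.67, 15 members called). With the hepatocyte list as a covariate the median was 2.25 with 11 called. Hepatocyte list means did not overlap between Control (0.52 to 1.79) and GC (4.47 to 7.01), or between ICB (2.84 to 4.73) and Combination (4.79 to 10.67). That fit therefore extrapolates and cannot decide on liver tissue. Minus the median of all genes it was 1.65 at the lower of both scalings (14 called with TMM, 13 with quantile), which argues against scaling. With the macrophage and monocyte list as a covariate it was 1.42 with 18 called, which argues against a larger share of these cells as the whole cause. An interferon response to chemotherapy may be a biological difference, as a hypothesis found and tested on the same samples. Liver tissue stays open as a part of its source, and other cell types were not tested.

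Rps27 and its near-identical copy Rps27rt exchanged levels between libraries: Rps27 was low and Rps27rt high in GC replicates 1 to 3 and ICB replicate 1. The SD over libraries of the log2 sum of both was 0.861, against 4.06 and 3.58 alone and at most 0.955 in the ribosomal protein list. Reads shared between the copies and assigned differently could give this. A processing difference that reached many genes is argued against, as 0 other tested genes parted these libraries by at least 1 log2 (largest gap 0.463). No biological explanation was tested.

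Regroupings of the samples were fitted in the same way. For the main effects, the interaction and the F test, 100 splits were drawn. The real grouping called the most genes for chemotherapy (429, highest other split 30) and for blockade (26, highest other 10), each as many in 1 of 100. That share is the smallest these splits can give. It does not tell treatment from a chance difference in liver, intestinal or muscle tissue between the groups. For the 2 interaction genes and the 233 genes of the F test as many came in 3 and 2 of 100, but the highest other splits called more than the real grouping (28 and 287), so neither count is set apart from regrouped samples. The blockade count was 0 without GC replicate 1, ICB replicate 2 or 3 or the muscle-rich pair and with the hepatocyte list mean as a covariate (limma, 331 to 565 genes at an unadjusted p under 0.05). It was 2 to 41 without any other Control, GC or ICB library and 1237 without Combination replicate 1. The chemotherapy count was 162 to 245 without any 1 Control, GC or ICB library and 1737 without Combination replicate 1, and with that covariate 53 of the 429 genes were among the 380 called. The interaction count was also 0 without any Control library, GC replicate 1 or 2, or ICB replicate 2 or 3 (limma, 615 to 1052 genes at an unadjusted p under 0.05). Chance cannot be excluded for the list counts: 18 lists for chemotherapy (highest other 34, as many in 48 of 100), 15 for blockade (35, in 65) and 22 for the interaction (35, in 32). Which samples the interaction split with 28 genes set apart was not examined.

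For comparisons of 3 samples against 3 the 10 splits cannot give a share under 0.05. Genes called in the real and the highest other split were 1 and 1 for GC against Control (as many in 2 of 10), 0 and 1 for ICB against Control (10 of 10), 504 and 1032 for Combination against Control (2), 85 and 339 for Combination against GC (2) and 286 and 1 for Combination against ICB (1). Lists were 26 and 28 (3), 36 and 36 (2), 20 and 28 (5), 11 and 26 (9) and 17 and 25 (5). The split with 1032 genes set Control replicates 2 and 3 with Combination replicate 1 apart, and the split with 339 set GC replicate 3 with Combination replicates 2 and 3 apart, which points to a structure of the samples.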

How the results depend on the processing

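The hepatocyte share covariate, pseudocount of 0.1 and fits without the muscle-rich, liver-rich or Combination libraries were chosen after the data were seen. Values in brackets are log2 differences of genes that changed sign, and median log2 differences of lists whose median or test changed direction. Where no construction is named beside a value, the cause was not tested. Counts of genes and lists not named under a setting were within 1.5 times those reported, which does not say that the genes were shared. With the hepatocyte list mean as a covariate 53 of the 429 genes of the chemotherapy main effect were among the 380 called, and 99 of the 286 of Combination against ICB among 289. Leaving out the liver-rich Combination libraries left only the intestine-rich replicate 1 in that group, so counts are not given for that setting. With the hepatocyte share 249 of the 429 were among 383, and under TMM 281 of the 429 were among 411. Gene counts are from limma, and where one of the counts below is 0, between 103 and 2081 genes had an unadjusted p under 0.05. Depth is unknown, so what it limits cannot be stated. The edgeR and DESeq2 alternatives were not run because read counts could not be recovered. Sample weights by the default method did not converge, and after its calls had been seen the gene-by-gene method was used in its place (weights 0.108 for Combination replicate 2 to 6.45 for ICB replicate 3).

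Leaving out each library in turn, 35 of 102 named called genes and 79 of 165 called lists kept their call and direction in all 12 fits. GC against Control gave 0 (without Control replicate 2 or 3, any GC library, ICB replicate 2 or Combination replicate 3) to 183 genes. Combination against Control gave 219 (without Control replicate 2) to 3167 and Combination against GC 24 (without GC replicate 1) to 3014. Combination against ICB gave 108 (without ICB replicate 2) to 2050 and the chemotherapy main effect 162 (without GC replicate 3) to 1737. The blockade main effect gave 0 (without GC replicate 1 or ICB replicate 2 or 3) to 1237. The interaction gave 0 (without any Control library, GC replicate 1 or 2, or ICB replicate 2 or 3) to 812. Any difference among the groups gave 131 (without Control replicate 2 or 3) to 1806. Each highest count came without Combination replicate 1. List counts were 9 (without Combination replicate 1) to 18 (without Combination replicate 3) for Combination against GC, 12 (without GC replicate 1) to 23 (without GC replicate 2) for the blockade main effect and 8 (without Combination replicate 1) to 27 (without GC replicate 1) for the interaction. Values that turned ranged as follows: Krt19 in GC against Control -0.029 (without Control replicate 2 or Control replicate 3) to 2.10 (without Control replicate 1); Mki67 in GC against Control -0.65 (without Control replicate 1) to 0.81 (without Control replicate 3); hypoxia response in ICB against Control -0.027 (without Control replicate 2) to 0.57 (without Control replicate 1); macrophages and monocytes in ICB against Control -0.28 (without Control replicate 1) to 0.65 (without Control replicate 2); immediate early genes in ICB against Control 0.0073 (without Control replicate 3) to 0.40 (without ICB replicate 2); Cdkn1a in ICB against Control -0.0023 (without Control replicate 3) to 0.82 (without Control replicate 1); Mki67 in ICB against Control -1.16 (without Control replicate 1) to 0.30 (without Control replicate 3); Cdkn1a in Combination against Control -0.39 (without Control replicate 3) to 0.42 (without Control replicate 1); Mki67 in Combination against Control -1.34 (without Control replicate 1) to 0.12 (without Control replicate 3).

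With a pseudocount of 0.5, genes called were 1 for the interaction. With a pseudocount of 10, genes called were 238 for Combination against Control, 174 for Combination against ICB, 166 for the chemotherapy main effect, 11 for the blockade main effect, 6 for the interaction and 117 for any difference among the groups. Krt19 turned in GC (-0.044) and ICB (-0.015) against Control. With a pseudocount of 0.1, genes called were 16 for Combination against GC, 9 for the blockade main effect and 0 for the interaction. Without a filter, genes called were 3 for GC against Control and 7 for the interaction. With a mean of at least 10 FPKM (fewer genes tested), genes called were 3 for GC against Control, 268 for Combination against Control, 3 for Combination against GC, 84 for Combination against ICB, 146 for the chemotherapy main effect, 4 for the blockade main effect, 0 for the interaction and 69 for any difference among the groups. Lists called were 14 for GC against Control, 21 for ICB against Control, 9 for the blockade main effect and 13 for the interaction. With a mean of at least 50 FPKM (fewer genes and list members tested), genes called were 122 for Combination against Control, 0 for Combination against GC, 7 for Combination against ICB, 30 for the chemotherapy main effect, 1 for the blockade main effect, 0 for the interaction and 10 for any difference among the groups. Lists called were 10 for GC against Control, 5 for ICB against Control, 6 for Combination against Control, 4 for Combination against GC, 7 for Combination against ICB, 7 for the chemotherapy main effect, 4 for the blockade main effect and 6 for the interaction. The correlation across genes was 0.674 for the chemotherapy effect and 0.447 for the blockade effect. Alternatively activated macrophages (0.32) turned in GC against Control. Platinum transport and detoxification turned in Combination against ICB (-1.11) and the interaction (-1.33).

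With TMM rescaling, genes called were 0 for GC against Control, 48 for Combination against GC and 2 for the blockade main effect. Lists called were 20 for Combination against GC. Cdkn1a (0.19) turned in Combination against Control. With quantile normalization, genes called were 0 for GC against Control, 858 for Combination against Control, 496 for Combination against ICB, 1078 for the chemotherapy main effect, 9 for the blockade main effect and 6 for the interaction. Without an intensity trend, genes called were 0 for GC against Control and 9 for the interaction. With sample weights, genes called were 1052 for GC against Control, 1277 for ICB against Control, 4269 for Combination against Control, 4028 for Combination against GC, 3472 for Combination against ICB, 2960 for the chemotherapy main effect, 4197 for the blockade main effect, 2164 for the interaction and 6084 for any difference among the groups. Lists called were 8 for Combination against ICB and 13 for the interaction. Hypoxia response (0.051) and Cdkn1a (0.33) turned in Combination against Control. Cholangiocyte and tumour epithelium (-0.78) and unfolded protein response (-0.17) turned in the interaction. Mki67 (-0.49) turned in GC against Control. With only the compared groups in the fit, genes called were 3 for GC against Control, 94 for Combination against Control, 3 for Combination against GC and 27 for Combination against ICB.

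With the hepatocyte list mean as a covariate, genes called were 574 for GC against Control, 239 for Combination against Control, 224 for Combination against GC, 0 for the blockade main effect and 133 for the interaction. Lists called were 15 for GC against Control, 17 for ICB against Control and 9 for the blockade main effect. Hepatocytes (0.0079), complement (0.35) and DNA damage repair (0.48) turned in GC against Control. Hepatocytes (-0.17), complement (0.016), Kupffer cells (-0.11), erythrocytes and erythroid cells (0.99), G1/S and DNA replication (0.39), plasma cells (0.31) and plasmacytoid dendritic cells (-0.068) turned in ICB against Control. Hepatocytes (-0.79), complement (-0.79), platinum transport and detoxification (0.34), Kupffer cells (0.23) and liver sinusoidal endothelial cells (0.39) turned in Combination against Control. Hepatocytes turned in Combination against GC (-0.42) and ICB (-0.17). Hepatocytes (-0.36), complement (-0.0066), platinum transport and detoxification (0.31) and Kupffer cells (0.22) turned in the chemotherapy main effect. Hepatocytes (-0.053), Kupffer cells (0.0033), interferon gamma response (-0.092), liver sinusoidal endothelial cells (-0.11), erythrocytes and erythroid cells (-0.31), G1/S and DNA replication (0.23) and complement (-0.29) turned in the blockade main effect. Alb (-0.80) turned in GC against Control. Alb (-0.16) and Mki67 (0.77) turned in ICB against Control. Alb (-0.68), Apoc1 (-0.19), Ttr (-0.72), Msln (0.22), Gclc (-1.22), Fgl1 (-0.75), Cd274 (0.047), Cdkn1a (0.14) and Mki67 (2.13) turned in Combination against Control. Ces1c (-0.12) and Fgl1 (-1.11) turned in the chemotherapy main effect. Hepatocyte list genes lose their difference under this covariate by construction.

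With the hepatocyte share of FPKM as a covariate, genes called were 263 for GC against Control, 207 for Combination against Control, 35 for Combination against GC, 115 for Combination against ICB, 3 for the blockade main effect and 136 for any difference among the groups. Kupffer cells (-0.11) turned in Combination against GC. Interferon gamma response (-0.0097), G1/S and DNA replication (-0.012) and complement (0.048) turned in the blockade main effect. Ribosomal proteins (0.073) turned in the interaction. Cd274 (0.0303), Cdkn1a (0.18) and Mki67 (0.67) turned in Combination against Control. Without the muscle-rich pair (fewer samples), genes called were 0 for GC against Control, 149 for Combination against Control, 15 for Combination against GC, 152 for Combination against ICB, 113 for the chemotherapy main effect, 0 for the blockade main effect, 0 for the interaction and 95 for any difference among the groups. Hypoxia response (-0.027) and Mki67 (0.15) turned in ICB against Control. Skeletal muscle (-0.0054) turned in the blockade main effect. Without the liver-rich Combination pair (fewer samples), genes called were 254 for GC against Control, 260 for Combination against GC, 881 for the chemotherapy main effect, 228 for the blockade main effect, 226 for the interaction and 428 for any difference among the groups. Lists called were 6 for the blockade main effect. The correlation across genes was 0.2003 for the chemotherapy effect and -0.183 for the blockade effect. Hepatocytes (-1.48), Kupffer cells (-0.52) and liver sinusoidal endothelial cells (-0.23) turned in Combination against GC. Erythrocytes and erythroid cells (-0.33), G1/S and DNA replication (-0.017) and complement (-0.0902) turned in the blockade main effect. Ribosomal proteins (0.037) turned in the interaction. Gclc (-0.086), Cdkn1a (0.16) and Mki67 (0.69) turned in Combination against Control. Without the Combination libraries, genes called were 297 for GC against Control.

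Whether the replicate numbers pair the samples is not settled. Same-numbered samples had a median correlation of deviations of 0.0346 (from -0.236 to 0.416, 8 of 18 pairs above 0.1), against -0.0307 for differently numbered samples. Of 12 samples, 6 correlated best with their own number. By the description numbers the median was 0.0654 (4 of 13 pairs above 0.1), against -0.0367 for other pairs. With the title number as a replicate block, genes called were 3 for GC against Control, 53 for Combination against GC, 10 for the blockade main effect and 0 for the interaction. With the description number as a block they were 31 for Combination against GC, 131 for Combination against ICB, 186 for the chemotherapy main effect, 1 for the blockade main effect, 0 for the interaction and 131 for any difference among the groups. The other counts of genes and lists were within 1.5 times those reported, but under the description block the gene called for GC against Control was not Cygb (limma adjusted p = 0.0594). Permuting within title numbers, the separation gave p = 0.00525 (permutation test).

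With an estimated correlation camera called 0 lists in any comparison. Fry's counts are given above.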

Other observations

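The genes and lists below were chosen after their values were seen, and no explanation for them was tested. Dendritic cell genes were higher as a group in GC than in Control, with 0 members past the threshold over all genes. Type 2 conventional dendritic cell genes had a median log2 difference of 1.43 between GC and Control over 6 genes (adjusted p = 0.000365, adjusted p = 0.385 with an estimated correlation), with 4 up when adjusted over the list alone. Type 1 conventional dendritic cell genes had a median of 1.06 over 5 genes (adjusted p = 0.0103, adjusted p = 0.385 with an estimated correlation), with 3 up when adjusted over the list alone. The cGAS-STING pathway list, which senses DNA in the cytosol, had a median of 0.95 over 9 genes (adjusted p = 0.00283, adjusted p = 0.482 with an estimated correlation), with 1 up when adjusted over the list alone. In Combination against Control the type 2 and type 1 lists had medians of 0.35 and -0.24 and were not called (adjusted p = 0.382 and 0.659, adjusted p = 0.873 and 0.903 with an estimated correlation). The T cell chemokine Cxcl10 stood at 1.83 ± 2.25, 8.38 ± 7.44, 0.907 ± 0.499 and 5.39 ± 1.27 FPKM in Control, GC, ICB and Combination.

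Alternatively activated macrophage genes were higher as a group in ICB than in Control, with a median of 0.84 over 14 genes (adjusted p = 1.73e-07, adjusted p = 0.105 with an estimated correlation) and 0 members past either threshold. Cholangiocyte and tumour epithelium genes had a median of 1.66 over 14 genes in Combination against Control (adjusted p = 0.000267, adjusted p = 0.421 with an estimated correlation), with 1 up over all genes and 2 up when adjusted over the list alone. The mean log2 value of that list relative to Control was 3.08 in the intestine-rich Combination replicate 1 and 1.13 and 1.199 in replicates 2 and 3, and without replicate 1 the adjusted p was 0.0147. The p53 target, mitosis and gemcitabine transport lists were called by camera in none of the comparisons, while fry's test for change in either direction called p53 targets for Combination against Control (limma adjusted p = 0.0491) and the chemotherapy main effect (limma adjusted p = 0.0235). The p53 target list had a median of 0.49 over 23 genes in GC against Control (adjusted p = 0.0819, adjusted p = 0.577 with an estimated correlation) and -0.16 in Combination against Control (adjusted p = 0.428, adjusted p = 0.903 with an estimated correlation), where 2 members rose over all genes and the list's test pointed up. Mitotic genes had medians of 0.24 and -0.52 over 25 genes (adjusted p = 0.999 and 0.445, adjusted p = 1.00 and 0.985 with an estimated correlation), and the test pointed down in both. Genes of gemcitabine transport and metabolism had medians of 0.07 and -0.18 over 13 genes (adjusted p = 0.870 and 0.921, adjusted p = 0.984 and 0.997 with an estimated correlation). Glycolysis genes had a median of -1.15 over 16 genes in Combination against Control (adjusted p = 0.000527, adjusted p = 0.714 with an estimated correlation). Over all genes 0 passed the threshold, and 11 were down when adjusted over the list alone. Relative to the Control mean the list was at -2.30 in the liver-rich Combination replicate 2 and -0.53 and -0.66 in replicates 1 and 3.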
